A study of Mus musculus with 3 samples.

How the data were processed

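Gene expression in whole brown adipose tissue of 10-week-old male mice was measured on 3 two-colour Agilent arrays. On each array, RNA of an Ad-Lkb1 mouse sample carried the dye Cy5 and RNA of a wild-type littermate sample carried Cy3, per the labels. LKB1, the product of Stk11, is the deleted kinase named in the series title. The design text gives 3 biological replicates of each genotype, so an array is a pair of 1 Ad-Lkb1 and 1 wild-type sample. The labels name the strain as C57BL/6J for Ad-Lkb1 and as C57BL/6 for wild type. All arrays had the same dye orientation, so dye and genotype were not separated by the design, and strain name and genotype were not separated either. All arrays came from 1 slide and 1 scan, so slide and scan could not be tested as blocks.

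The deposited scanner files hold, per the file headers, median spot and local background intensity in both channels, made with Agilent Feature Extraction (version 11.5 per the submitters' processing notes). They also hold processed intensity values, background-subtracted and dye-normalized by that software, and a log10 ratio of red over green, per the file headers. The deposited value table was matched to that log10 ratio by feature number. The correlation was 1.0 on each array, the largest difference was 0.0049 in log10 units, and each column's median was 0.0. Its scale (log10), centring and direction (Cy5 over Cy3) were therefore known. The software had set the ratio to 0 on 26.8% to 27.8% of the non-control features, which holds for the deposited value table as well. The array is annotated on mm9 in the file headers, and no coordinates were used.

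Depth on an array is signal over background. The median green signal was 51.0, 51.5 and 53.5 on arrays 1 to 3 against a median green background of 44.0, 43.5 and 43.0. The median red signal was 21.0, 23.0 and 23.0 against a red background of 17.0. Of 59304 or 59305 non-control features per array, 46.7%, 46.7% and 46.8% were well above background in green and 47.7%, 51.3% and 51.2% in red. No spot was saturated (0 in either channel). The slope of observed against expected log ratios of the spike-in probes was 0.886, 0.889 and 0.879, as the scanner's own statistics give it. The number of arrays, 3, limits the precision of every ratio.

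Ratios were computed in R 4.3.3 with limma 3.58.1. The plan named mean signals, or medians where means were lacking. The files hold medians, so these were used. Background was corrected with normexp (offset 50) on all spots, followed by loess within each array with control spots at weight 0, and no scaling between arrays. Control spots and spots marked as outliers were left out, as were 1 empty feature of array 1 and 2 incomplete features of array 3. Spots of a probe were averaged. A probe was kept if it was well above background on all 3 arrays in at least 1 channel, which left 25034 of 55680 probes. The planned gene name column was not in these files. Gene symbols were taken from a RefSeq table (assembly GRCm38.p6) by unversioned accession. Of 29796 probes with a RefSeq accession, 28026 matched 1 symbol, giving 21154 symbols, and 27654 probes kept the file's own name, 16193 of them a genomic interval. A gene was represented by its kept probe of highest mean intensity, which gave 19331 genes and unnamed features, 13132 with a symbol. Folds of dim genes are understated by the offset.

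The log2 ratio of Ad-Lkb1 over wild type was tested against 0 with limma (lmFit and eBayes, intercept only), and p-values were adjusted by Benjamini-Hochberg over all 19331 features, with a threshold of 0.05. Because the ratio is taken within an array, the test is paired. The SE given is that of the moderated fit. Where a channel was well above background on 0 of the 3 arrays, a fold is a bound. Where it was so on some arrays only, the measured ratio is given with their number. The brighter channel's mean was set against the higher of the dim probe's own level and the lowest level among probes well above background, per channel after loess and Aquantile normalization. Where the dim probe's own level was the higher, the bound equals the measured ratio and is not a firm minimum. Such bounds are open to dye bias.

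The 24 tested gene lists and a list of male-specific genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (correlation preset at 0.01), with camera using an estimated correlation, and with fry, with adjustment over the 24 lists. Named genes were Stk11 and Ucp1, the 8 highest and 8 lowest ratios among genes past the threshold with the same sign on all arrays, up to 4 members with the smallest p of each list past the camera threshold, and up to 2 of each other list. Names of clones and predicted genes were passed over, and a gene that the rule names is not reported here.

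The procedure was tested on simulated intensities of 3 arrays with a dye curve and 200 changed genes among 19331. At a log2 ratio of 2, 97.0% of 66 changed genes were recovered, at 1 it was 64.2% of 67, and at 0.5 it was 1.49% of 67. The Benjamini-Hochberg cut on p depends on how many genes change, and 1681 features passed in the real data. These recovered shares, from a single simulated data set, therefore do not give the sensitivity of the real fit. Of 122 genes called, 14 (11.5%) were not among the changed ones, and 0 had the wrong sign. That share was above the 0.05 set as the threshold on the adjusted p. The share of unchanged genes among those past the threshold in the real data may therefore also be above 0.05. None (0) of the 24 lists, which were not shifted as lists, was called. The simulated noise was independent between genes, whereas the estimated correlation within the real interferon response list was 0.98. The simulation therefore did not test list calls for genes that vary together. Its dye curve depended on intensity alone, so probe-specific dye bias was not simulated.

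The alternatives tried were the software's processed signals, no background subtraction, an offset of 10, median centring, scaling between arrays, other filters on dim probes, the mean of a gene's probes, an intensity trend in the variance, the deposited value table, probes in place of genes, the channels as separate samples without pairing, and leaving out each array. A fit with the muscle genes' median ratio as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.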

Results

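The data are log2 ratios of expression in whole brown adipose tissue, the heat-producing fat, of Ad-Lkb1 mice over wild-type littermates. There were 3 arrays, each holding 1 sample of either genotype from 10-week-old males on regular chow. The single comparison asks how deletion of LKB1, a kinase upstream of AMPK, changed gene expression in this tissue. Between 46.7% and 51.3% of the features were well above background in a channel. Across genes, which are not independent replicates, the ratios of arrays 1 and 2 correlated with Pearson's r = 0.73, those of arrays 1 and 3 with r = 0.36, and those of arrays 2 and 3 with r = 0.50.

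Stk11, which encodes LKB1, fell by 1.20 on the log2 scale (SD 0.056, n = 3 arrays), a level 2.30-fold higher in wild type (limma, adjusted p = 0.0105). Its ratio was -1.26, -1.17 and -1.17 on arrays 1 to 3. Without array 1 the mean was -1.17 and without array 2 it was -1.22, neither past the threshold (adjusted p = 0.124 and 0.0877). A single kept probe measured it, and where it lies relative to the deleted part was not analysed here. Ucp1, the uncoupling protein of brown fat, rose 2.78-fold (log2 ratio 1.48 ± 0.19 SD, n = 3, adjusted p = 0.0114).

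Of 19331 genes and unnamed features tested, 1681 passed the threshold, 923 higher and 758 lower in Ad-Lkb1 tissue. Among the 1396 of these with a gene symbol, 752 were higher and 644 lower, and 222 and 105 of them differed by at least 1 on the log2 scale. A fold is only a bound for 41 of the 1681, and for 70 others a channel was well above background on some arrays only. Median centring in place of loess moved the median of all genes to -0.42. It leaves any change of the dye ratio with intensity in place, so the shift need not be the same for every gene. Stk11 went from -1.20 to -1.86 and Ucp1 from 1.48 to 0.80. The median of complexes II to V went from 0.21 to -0.48. Each of these moved further than the median of all genes, so values given with median centring below cannot be read against -0.42 alone. Without array 1 or without array 2, limma called 0 genes, with 3929 and 3563 at an unadjusted p under 0.05, and without array 3 it called 2041, of which 1175 were shared.

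The 8 highest log2 ratios ran from 2.81 to 4.39. Lgals3, which encodes the galactose-binding lectin galectin-3, rose by 4.39 on the log2 scale (SD 1.12, adjusted p = 0.018). Gdf15, a stress-responsive secreted factor, rose 12.4-fold and Atf3, a stress-induced transcription factor, 7.37-fold. Several genes of this set are known from macrophages and other myeloid cells, among them the protease Ctss (11.3-fold), the receptor Trem2 (10.5-fold) and Ms4a7 (8.20-fold). Adam8, a membrane metalloprotease, rose 8.38-fold. Lilrb4a had a log2 ratio of 2.81, and since it has a close paralog, which gene its probes measured is uncertain. Among these 8 genes, Ctss and Atf3 differed most between arrays. Ctss had a log2 ratio of 4.87 on array 2 and 1.78 on array 3, and Atf3 had 3.81 and 1.58. These 2 genes did not pass the threshold without a filter on dim probes or with the deposited value table, and Lilrb4a did not without the filter. Over the alternatives the log2 ratio of Gdf15 ranged from 3.11 to 6.06, that of Adam8 from 2.55 to 4.96 and that of Trem2 from 2.82 to 4.68, each highest with the software's processed signals.

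**Figure D1:**
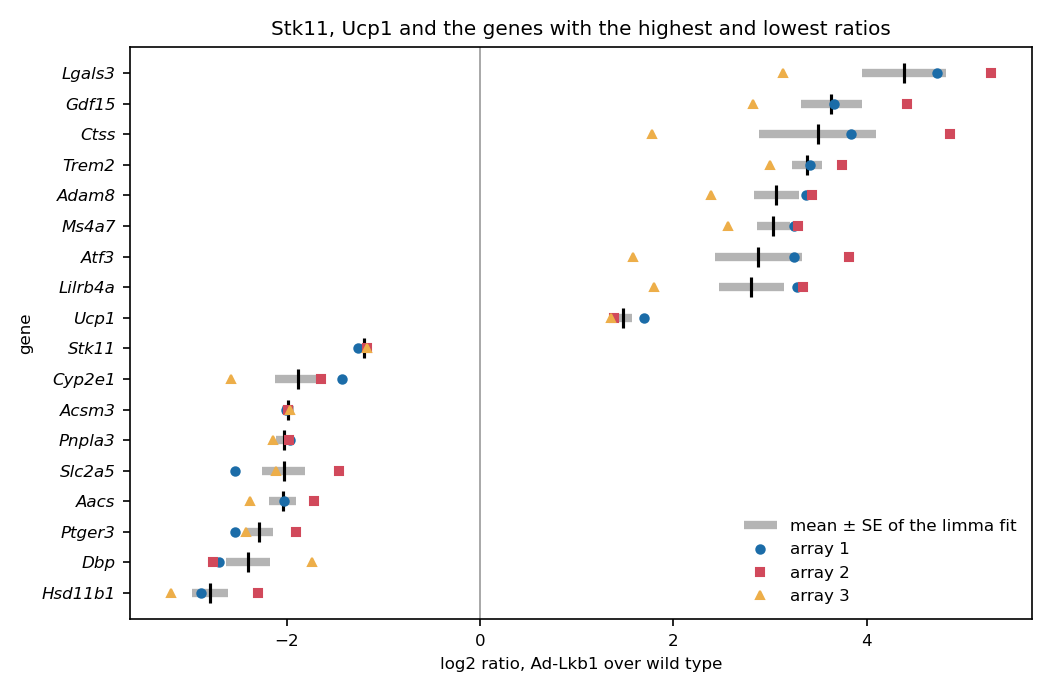
Log2 ratio of Ad-Lkb1 over wild type (horizontal axis) for Stk11, Ucp1 and the 8 genes with the highest and the 8 with the lowest ratios (vertical axis). Points are the 3 arrays, black marks the means and grey bars the SE of the limma fit. All ratios of a gene share a sign, from a mean of -2.79 for Hsd11b1 to 4.39 for Lgals3.

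The 8 lowest log2 ratios ran from -2.79 to -1.88. Hsd11b1, which regenerates active glucocorticoid, was 6.94-fold higher in wild type (log2 ratio -2.79 ± 0.46 SD, n = 3, adjusted p = 0.0115). Dbp, a transcription factor of the circadian output, was 5.28-fold higher in wild type, and Ptger3, a prostaglandin E2 receptor, 4.89-fold. Aacs, which activates acetoacetate for lipid synthesis, the fructose transporter Slc2a5 and the lipase-family gene Pnpla3 had log2 ratios of -2.04, -2.03 and -2.03. Acsm3, an acyl-CoA synthetase, had -1.99 and the cytochrome P450 gene Cyp2e1 had -1.88. Pnpla3 had -1.46 with the mean of its probes, not past the threshold, and Slc2a5 and Cyp2e1 did not pass without a filter on dim probes.

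Genes of fatty acid and triglyceride synthesis were lower as a group. Of 22 measured, 11 fell and 0 rose (14 lower and 1 higher adjusted over the list alone), and the list's median log2 ratio was -0.62, from -1.26 to -0.50 over the alternatives (camera adjusted p = 2.98e-09). The adjusted p was 0.368 with an estimated correlation. Pnpla3 (-2.03, or -1.46 with the mean of its probes), the acetate-activating Acss2 (-1.70), fatty acid synthase Fasn (-1.40 ± 0.092 SD, adjusted p = 0.0105) and the acetyl-CoA carboxylase Acacb (-1.37) had the smallest p. All 18 measured genes of cholesterol synthesis and its regulation had ratios below 0, and 10 of them fell (17 adjusted over the list alone), with a median of -0.90, from -1.58 to -0.71 over the alternatives (camera adjusted p = 1.82e-10). With an estimated correlation the adjusted p was 0.388. Fdft1, which makes squalene, fell by 1.74 on the log2 scale (SD 0.029, adjusted p = 0.0105), and Insig1, Lss and Sc5d had log2 ratios of -1.58, -1.06 and -1.04.

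Genes of lipolysis and lipid uptake went both ways, with 5 of 18 lower and 2 higher (9 and 3 adjusted over the list alone). The median was -0.23, from -0.93 to -0.15 over the alternatives (camera adjusted p = 0.0179), and the adjusted p was 0.637 with an estimated correlation. The lipolysis inhibitor G0s2 (-1.39), the lipid droplet coat gene Plin4 (-1.18), the lipoprotein receptor Vldlr (-1.05) and the fatty acid-binding Fabp3 (-0.98) fell. Camera no longer called this list without array 2. Fatty acid oxidation genes did not pass as a list (camera adjusted p = 0.152), with 6 of 25 higher and 2 lower (9 and 3 adjusted over the list alone) and a median of 0.12 that turned to -0.53 with median centring. Acsl5 had -1.42 and the mitochondrial carrier Ucp3 had 1.06, but the other kept probe of Ucp3 did not share its sign, and the mean of its probes was 0.16, not past the threshold. Ucp3 had 0.40 with median centring and did not pass then either.

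Brown fat thermogenesis and identity genes were split. Of 25 measured, 8 rose and 4 fell (11 and 8 adjusted over the list alone), and the list as a whole did not pass (median 0.12, or -0.46 with median centring, camera adjusted p = 0.225). Ucp1 rose, as given above, while Ppara, the nuclear receptor of fatty acid oxidation, fell by 1.69 on the log2 scale (SD 0.31, adjusted p = 0.0134). Among genes of respiratory complexes II to V, 8 of 39 rose and 0 fell (12 higher and 1 lower adjusted over the list alone), with a median of 0.21 that turned to -0.48 with median centring (camera adjusted p = 2.64e-04, or adjusted p = 0.637 with an estimated correlation). The ATP synthase subunit Atp5b had 1.03 and Sdhb of complex II had 0.92, which became 0.35 and 0.23 with median centring, and neither passed the threshold then or with the deposited value table. Uqcrc2 (0.64) and Uqcrh (0.58) of complex III turned to -0.042 and -0.096 with median centring. Camera lost this list with median centring, with the software's processed signals, without background subtraction, with an offset of 10 and with the deposited value table. Complex I did not pass (37 genes, 0 past the threshold over all genes or adjusted over the list alone, median 0.093, or -0.59 with median centring, camera adjusted p = 0.173). Ndufa7 had -0.32 (adjusted p = 0.0715) and Ndufs6 had 0.32 (adjusted p = 0.0847), or -0.37 with median centring.

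Of the LKB1 and AMPK-family list, 1 of 25 genes fell, Stk11 itself (5 lower adjusted over the list alone). The list's median was -0.18, from -0.81 to -0.10 over the alternatives (camera adjusted p = 0.00921, or adjusted p = 0.368 with an estimated correlation), and camera no longer called it with the software's processed signals or the deposited value table. Prkag2, Prkaa2 and Strada had ratios of -0.80, -0.51 and -0.37, none past the threshold (adjusted p = 0.0589, 0.0669 and 0.0628). Glycolysis and glucose uptake genes had 6 of 20 higher and 3 lower (8 and 3 adjusted over the list alone). Their median was 0.24, or -0.43 with median centring (camera adjusted p = 0.0434, or adjusted p = 0.637 with an estimated correlation). Hexokinase Hk1 had 1.35 and Pgk1 had 0.68, or 0.64 and -0.014 with median centring, neither past the threshold then, whereas Pdk1, which inhibits pyruvate dehydrogenase, had -1.02 and Pfkl had -0.94. Camera lost the glycolysis list with median centring, with the software's processed signals, without background subtraction, with an offset of 10, with the mean of a gene's probes, with the deposited value table and without array 3.

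Target genes of CREB and CRTC, which the LKB1-dependent SIK kinases restrain, had 4 of 18 higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.63, from 0.054 with median centring to 1.08 over the alternatives (camera adjusted p = 6.41e-04, or adjusted p = 0.368 with an estimated correlation), but the list's median on array 3 was 0.0086. Pde4b, a cAMP phosphodiesterase, rose by 1.96 on the log2 scale, Pde10a by 1.44 and Crem by 0.94. With median centring Crem had 0.31, not past the threshold. Several other members changed sign between arrays, and those given next were picked after their values were seen. Fos had 3.58, 2.61 and -1.20 on arrays 1 to 3, and Egr1 had 2.72, 1.66 and -2.53. Per1 went the other way, with -0.52, -0.37 and 1.25. None of these passed the threshold. Of 21 genes of the amino acid response, driven by the transcription factor ATF4, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.46, from 0.087 with median centring to 1.01 over the alternatives (camera adjusted p = 1.91e-06, or adjusted p = 0.368 with an estimated correlation). Those with the smallest p were Gdf15 (3.64), Trib3 (1.62), the glutathione-degrading Chac1 (1.47) and Atf4 itself (0.94). Atf4 had 0.24 with median centring, and it did not pass the threshold then or with the deposited value table. Protein folding genes of the endoplasmic reticulum did not pass (1 of 20 higher and 1 lower, 2 and 1 adjusted over the list alone, median 0.10, or -0.57 with median centring, camera adjusted p = 0.0794). The chaperone Hspa5 had 0.60, or -0.11 with median centring, and Sel1l had -0.41.

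**Figure D2:**
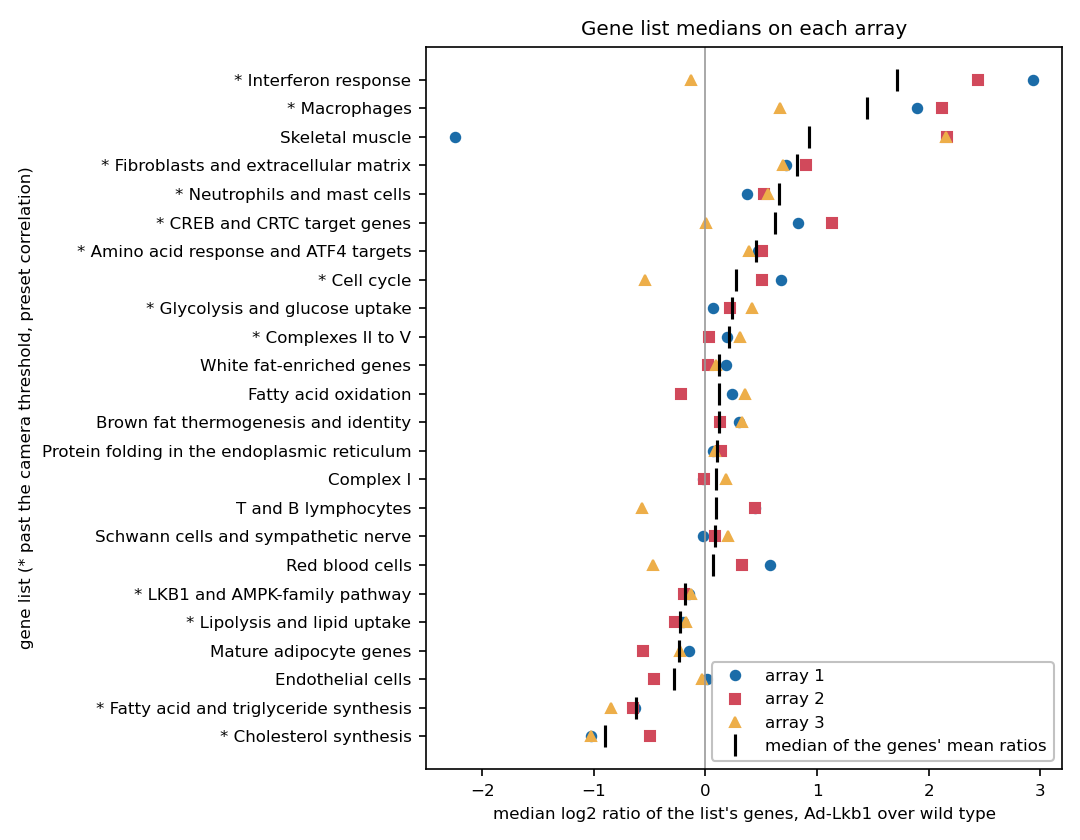
Median log2 ratio of Ad-Lkb1 over wild type (horizontal axis) of the measured genes of each of 24 lists (vertical axis). Coloured points are the 3 arrays, black marks the medians of the genes' mean ratios, and asterisks the 13 lists past the camera threshold with preset correlation. Cholesterol synthesis had the lowest median at -0.90, and the skeletal muscle list spread from -2.25 to 2.16.

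Macrophage markers were higher in Ad-Lkb1 tissue. Of 18 measured, 8 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 ratio of 1.45, from 0.81 to 2.42 over the alternatives (camera adjusted p = 4.84e-08, or adjusted p = 0.616 with an estimated correlation). The list's median was 1.90, 2.12 and 0.67 on arrays 1 to 3. Trem2 (3.39 ± 0.37 SD, adjusted p = 0.0105), Gpnmb (2.66), the lectin Clec4d (2.35) and the lysosomal protein Cd68 (2.24) had the smallest p. In wild type, Clec4d was well above background on 1 of the 3 arrays and Gpnmb on 2, and over the alternatives their log2 ratios ranged from 1.99 to 5.81 and from 2.25 to 5.10. Neutrophil and mast cell genes had 5 of 11 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.66, from 0.27 to 2.22 over the alternatives, camera adjusted p = 0.0017, or adjusted p = 0.368 with an estimated correlation). The mast cell proteases Mcpt4 (1.47) and Cpa3 (0.99) and the calcium-binding S100a8 (2.17), abundant in neutrophils, rose. The 1 gene that fell was the receptor Kit (-1.22, adjusted p = 0.0421), named here after its values were seen. Cpa3 was well above background in wild type on 2 of the 3 arrays. Over the alternatives the log2 ratio of Cpa3 ranged from 0.76 to 2.97, that of S100a8 from 1.66 to 3.24 and that of Mcpt4 from 0.96 to 2.22. Cma1 was not well above background in wild type, and its bound of 1.58-fold equalled its measured ratio (log2 ratio 0.66). Over the alternatives its log2 ratio ranged from 0.52 to 2.86, so that bound is not a firm minimum.

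Extracellular matrix and fibroblast genes rose with the largest share of any list, 15 of 21, and 0 fell (19 and 0 adjusted over the list alone). The median was 0.82, from 0.18 with median centring to 1.19 over the alternatives (camera adjusted p = 2.2e-11, or adjusted p = 0.368 with an estimated correlation), and it was 0.72, 0.90 and 0.69 on the arrays. The collagen gene Col3a1 rose by 1.17 on the log2 scale (SD 0.047, adjusted p = 0.0105), and Thbs1 and Col6a1 had log2 ratios of 0.98 and 0.79. The proteoglycan gene Lum rose 2.83-fold. Median centring left Col6a1 at 0.083, not past the threshold.

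**Figure D3:**
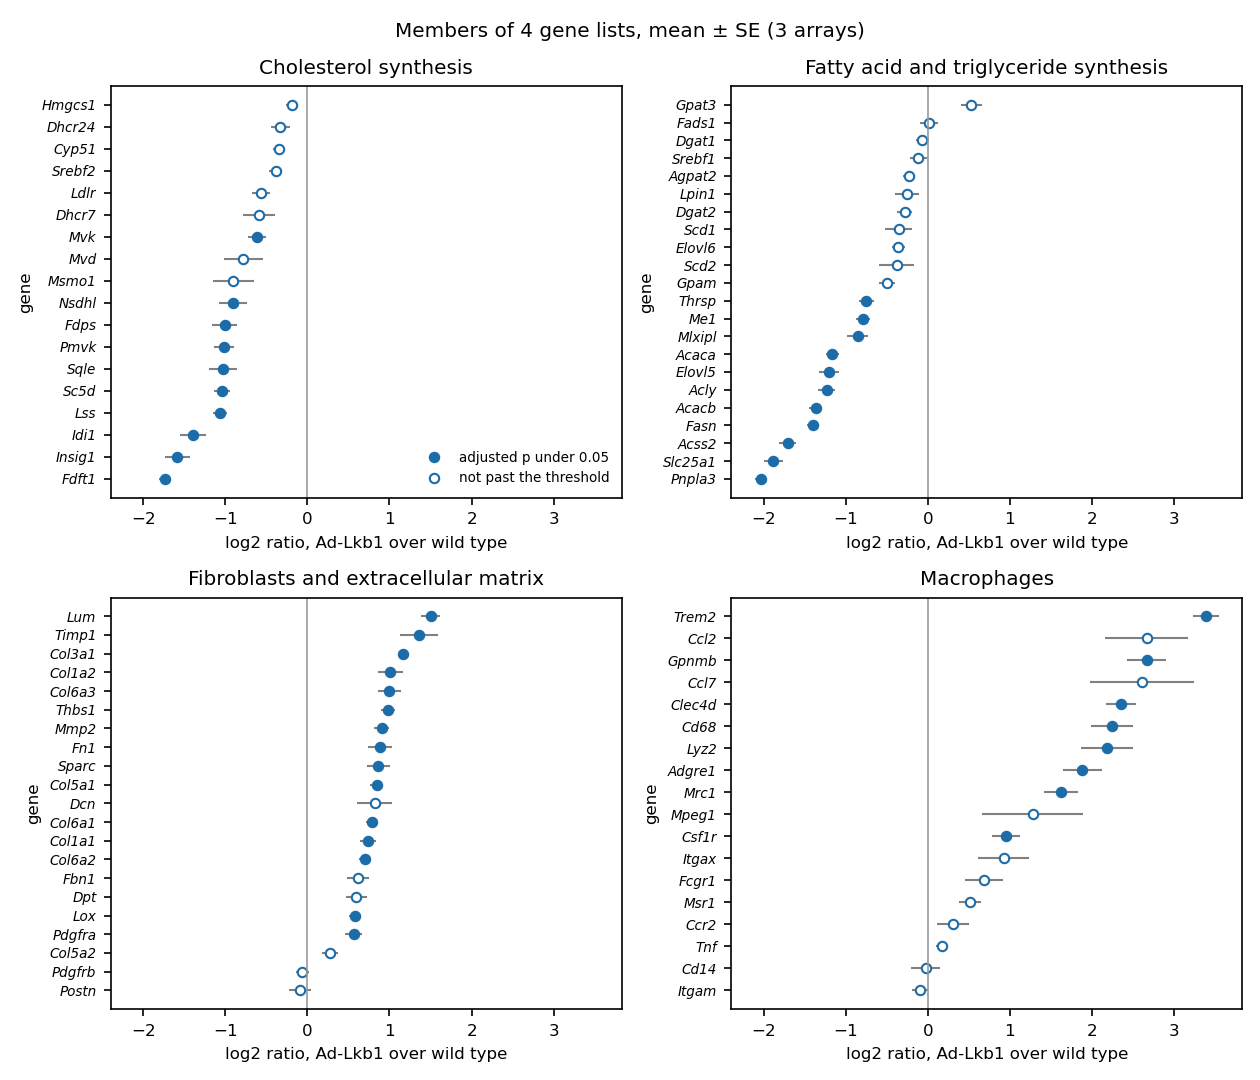
Mean log2 ratio of Ad-Lkb1 over wild type (horizontal axes) with its SE for each measured gene (vertical axes) of 4 lists, over 3 arrays. Filled points passed an adjusted p of 0.05. All 18 cholesterol synthesis genes lie below 0, and 16 of the 18 macrophage markers lie above it.

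Interferon response genes had a median of 1.71, from 1.15 to 2.74 over the alternatives (camera adjusted p = 2.83e-05, or adjusted p = 0.637 with an estimated correlation), but the median was 2.94 and 2.45 on arrays 1 and 2 and -0.13 on array 3. Of 21 measured, 2 rose and 0 fell (5 and 0 adjusted over the list alone), the antiviral genes Oasl1 (2.65) and Oas2 (1.43). Irf7 had 2.12 and Oas1a 2.94, not past the threshold (adjusted p = 0.0594 and 0.0647). The cell cycle list passed camera (median 0.28, from 0.043 to 1.02 over the alternatives, adjusted p = 0.0297, or adjusted p = 0.735 with an estimated correlation) with 0 of 21 genes past the threshold over all genes or adjusted over the list alone, and medians of 0.68, 0.51 and -0.54 on the arrays. Camera no longer called it without array 1 or without array 2. Mcm6 had 0.68, Cdc20 0.40, Ccne1 0.21 (or -0.26 with median centring) and Bub1b 0.16, none past the threshold.

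The remaining lists did not pass camera. Mature adipocyte genes had a median of -0.24, or -0.92 with median centring (3 of 18 lower and 1 higher, 7 and 3 adjusted over the list alone, adjusted p = 0.0592), with Tkt at -0.75 and Pcx, which encodes pyruvate carboxylase, at -0.60. White fat-enriched genes had 4 of 13 higher and 1 lower (4 and 2 adjusted over the list alone) and a median of 0.12 that turned to -0.17 with median centring (adjusted p = 0.0794). Among them Nnmt, which methylates nicotinamide, rose 6.38-fold and the synuclein gene Sncg 4.27-fold. Endothelial genes had a median of -0.28, or -0.90 with median centring (1 of 18 higher and 1 lower, as adjusted over the list alone, adjusted p = 0.152). The receptor Kdr had -0.42, and Vwf had 0.40, or -0.25 with median centring. Schwann cell and nerve genes had a median of 0.086, or -0.39 with median centring (1 of 9 higher and 1 lower, as adjusted over the list alone, adjusted p = 0.357), with Mal at 1.81 and tyrosine hydroxylase Th at -0.41. Lymphocyte genes had 0 of 11 past the threshold over all genes or adjusted over the list alone (median 0.093, or -0.20 with median centring, adjusted p = 0.558), with Ccr7 at 0.53. Their median was 0.44 on arrays 1 and 2 and -0.57 on array 3, and that of red blood cell genes was 0.58, 0.33 and -0.47 on arrays 1 to 3, so both lists, like the cell cycle and interferon lists, had a median below 0 on array 3 alone.

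Skeletal muscle genes differed between arrays more than with genotype. None of 13 passed the threshold (0 over all genes and 0 adjusted over the list alone, median 0.93, camera adjusted p = 0.173), and the list's median was -2.25 on array 1 and 2.16 on both other arrays. Myoglobin Mb had 1.41 ± 1.29 SD (adjusted p = 0.151) and Actn2 0.43. With that median as a covariate, limma called 0 genes, with 5237 at an unadjusted p under 0.05. Since the covariate in effect marked array 1, that fit cannot tell muscle from anything else that set array 1 apart. Red blood cell genes had 0 of 6 past the threshold over all genes or adjusted over the list alone (median 0.07, or -0.57 with median centring, adjusted p = 0.357). The near-identical Hba-a1 (0.16, or -0.52 with median centring) and Hba-a2 (0.80) cannot be told apart with certainty by such probes. Of 3 measured male-specific genes, 0 passed over all genes and 1 was lower adjusted over the list alone, with Eif2s3y at -0.35 and Ddx3y at -0.075, or 0.096 with the software's processed signals.

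No list (0 of 24) passed with an estimated correlation, where the lowest unadjusted p was 0.0544, and 0 lists had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom, unlike the test with preset correlation. A list lost there was therefore not necessarily lost through correlation among its genes. The LKB1 and AMPK-family list lost its call with an estimated correlation of -0.039, below the preset 0.01. That was the lowest estimate among the called lists. Others lay far above the preset, at 0.98 for interferon response, 0.96 for cell cycle, 0.73 for macrophage markers and 0.50 for complexes II to V. The preset test takes no account of such correlation, so its small p-values for these lists are to be read with caution. Fry, which asks whether a list's genes move one way on balance, called 7 lists, 6 of them among the 13 of camera. It did not call the other 7 of these 13, namely macrophage markers, CREB and CRTC targets and lipolysis (fry adjusted p = 0.124 each), complexes II to V (0.164), glycolysis (0.396), interferon response (0.407) and cell cycle (0.646).

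Apart from the fits that called 0 genes, genes named above lost the threshold as follows, in addition to the losses already given. Without a filter on dim probes these were Uqcrh, Acsl5, Ucp3, G0s2, Hk1, Pde10a, Chac1, Cd68, S100a8, Cma1, Oas2 and Oasl1. With the software's processed signals they were Sdhb, Uqcrc2, Uqcrh, Fabp3, Vldlr, Pfkl, Pgk1, Hspa5, Sel1l, Pcx, Kdr, Vwf and Th, and with the deposited value table Uqcrc2, Uqcrh, Ucp3, Vldlr, Pgk1, Hk1, Hspa5, Sel1l, Pcx, S100a8, Kdr, Vwf, Th and Oas2. Sel1l, Kdr, Vwf and Th lost it without array 3, Sel1l, Kdr, Th and Uqcrh without background subtraction and with an offset of 10, Uqcrc2 with that offset, Sel1l, Vwf and Th with an intensity trend in the variance model, and G0s2 without the pairing of the channels.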

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

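The covariate fit was chosen after seeing the data, and all other alternatives were chosen before the data were examined. The count of changed genes, 1681 (54.9% higher), was 1115 with the software's processed signals (79.4% higher), 1033 without a filter on dim probes, 813 with the deposited value table (65.4%), and 10097 with median centring (3.9% higher), which moved the median of all genes to -0.42. It was 0 with the muscle covariate and 0 to 2041 with 1 array left out (0 without array 1 or array 2). Both leave 1 residual degree of freedom fewer. An offset of 10 gave 66.9% higher, and leaving out array 3 gave 64.9%. Without the pairing of the channels, the count was 2932, of which 1612 were shared. The Stk11 log2 ratio lay between -1.86 and -1.17 in all 15 alternatives, with adjusted p from 6.88e-04 to 0.124. It was -1.22 with the muscle covariate (adjusted p = 0.0726) and -1.22 to -1.17 with 1 array left out, past the threshold only without array 3. The number of lists called, 13, was 12 to 17 in all alternatives except an estimated correlation, with 0, and fry, with 7.

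With median centring the sign turned for Ndufs6 (-0.37), Uqcrc2 (-0.042), Uqcrh (-0.096), Pgk1 (-0.014), Hspa5 (-0.11), Ccne1 (-0.26), Vwf (-0.25) and Hba-a1 (-0.52), and the camera direction for complex I (median -0.59) and protein folding (-0.57). The medians of complexes II to V, glycolysis, fatty acid oxidation, brown fat, white fat, lymphocyte, nerve and red blood cell genes also went below 0, with the camera direction kept. Since median centring leaves any change of the dye ratio with intensity in place, these turns cannot be read as genotype effects alone. Ddx3y had 0.096 with processed signals and 0.010 without array 1. Hba-a1 had -0.11 with the deposited value table and -0.016 without array 1 (up to 0.46 with another array left out). The camera direction of complex I turned with processed signals (median 0.013), without background subtraction (-0.0045), with an offset of 10 (-0.0076), with the deposited value table (-0.11) and without array 3 (0.011, up to 0.12 with another array left out), that of fatty acid oxidation with processed signals (0.049), that of lymphocytes without array 1 (-0.15) or array 2 (-0.16, up to 0.44), that of red blood cells without array 1 (-0.12, up to 0.45), and that of muscle without array 3 (-0.18, up to 2.16). Of lists not called, mature adipocyte genes passed in 8 of 16 alternatives and tests, white fat genes in 5, protein folding and muscle in 3 each, lymphocyte and endothelial genes in 2 each, and fatty acid oxidation and red blood cell genes in 1 each. The cause was not tested. For single named genes, 980 values kept direction and side of the threshold, 279 lost the threshold, 27 gained it and 12 turned. The median signal lay close to background, which limits the folds of dim genes.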

Other observations

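The tests of a lower share of adipocytes, of equal macrophage factors and of genes with a single probe were chosen only after the results were seen. The comparison with muscle genes and the minimum number of clock genes, which left the macrophage and clock hypotheses open, were also set after their values were seen. Genes in the next sentences were picked after their values were seen. Several genes known from liver secretion were higher in Ad-Lkb1 brown fat. The protease inhibitor genes Serpina1a and Serpina1c had log2 ratios of 2.57 (SE 0.14) and 2.23 (SE 0.11), and the major urinary protein genes Mup17, Mup4 and Mup19 had 2.63, 2.46 and 2.46. Members of both families are near-identical, so which member was measured is uncertain. Of 5 measured plasma protein genes of liver, on a list written after the first look, 0 passed the threshold, and their median was 0.08.

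Among the brown fat identity genes, the thyroid hormone-activating deiodinase gene Dio2 (2.07) and S100b (2.02) rose with Ucp1, while the potassium channel gene Kcnk3 (-0.75) and the thioesterase gene Acot11 (-1.25) fell. Among matrix genes Timp1, a protease inhibitor, had 1.36.

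Dye and genotype go together in this design, so the 1681 genes past the threshold were weighed against probe-specific dye bias. For the 453 called genes with another kept probe, the other probes had on average the sign of the call in 92.3% (Wilson interval 89.4% to 94.4%), against 70.9% of 3831 genes not called. The agreement in sign argues against dye bias of single probes as the whole cause for these genes, although probes of overlapping sequence could share a bias. The sizes were not matched. In the direction of the call, the other probes had a median log2 ratio of 0.37. The median absolute log2 ratio of the called probes was 0.632. How much of a called ratio is specific to its probe was not tested. For the 1228 called genes with 1 kept probe, Stk11 and Ucp1 included, dye bias and genotype cannot be told apart, because no array has the dyes swapped. Turning the sign of an array gives 4 choices, of which 1, the real one, gave as many genes (1681 against a highest other of 0), but 4 choices are too few for a share under 0.05.

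The rise of macrophage markers may reflect a larger share of macrophages, or changed expression in them, and either would be a hypothesis. A lower share of adipocytes, raising all other cell types alike, is argued against as the whole cause. The macrophage median lay 1.36 above the highest of the endothelial, lymphocyte and nerve medians. These lists were chosen after the results were seen. Against their pooled markers the macrophage median lay 1.47 higher, by 1.83, 2.18 and 0.71 on arrays 1 to 3. The 95% bootstrap interval of 0.65 to 2.36 came from resampling marker genes. It shows the spread over markers, not over arrays, and macrophage markers varied together (estimated correlation 0.73). Markers of other cell types rose too, with medians of 0.82 for matrix and fibroblast genes and 0.66 for neutrophil and mast cell genes. The matrix and fibroblast median was below the macrophage median on arrays 1 and 2 but not on array 3 (0.69 against 0.67). The comparison therefore does not exclude a cause that macrophages and fibroblasts share. Against the pooled markers of all 7 other cell types, matrix, neutrophil, muscle and red blood cell lists included, the difference was 1.18. It was 1.69, 1.65 and 0.38 on the arrays, and the 95% bootstrap interval, again over markers only, was 0.34 to 2.09. Equal factors for all markers were not seen, as their SD was 4.90 times their median SE. Muscle genes varied more than macrophage markers on array 1 (SD 1.72 against 1.20) and array 3 (1.83 against 0.98) but less on array 2 (0.99 against 1.26), so this comparison settles nothing, and more macrophages with unchanged expression stays open.

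The muscle genes' differences between arrays are consistent with muscle tissue in some samples, of either genotype. On each array at least 92.3% of the 13 genes shared a sign, negative on array 1 and positive on arrays 2 and 3, and the medians ranged over 4.41. Tnni2 had -4.57, 2.98 and 5.48 on arrays 1 to 3, and Myh4 had -4.50, 2.36 and 5.04. A difference in muscle gene expression within brown fat was not tested.

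Dbp fell and its antagonist Nfil3 rose (2.14), which raised the hypothesis that clock phase differed at collection. Without these, 33.3% of 3 genes of the Arntl phase were higher (Arntl at 1.27) and 88.9% of 9 genes of the Dbp phase were lower. With 3 genes in a phase the test leaves this open, and collection times were not analysed here.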
